A study of Bos taurus with 6 samples.

How the data were processed

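RNA was measured in granulosa cells from the dominant preovulatory follicle of 6 Hereford cows, 3 aged (multiparous) and 3 young (nulliparous heifers). Per the labels, each of 6 2-colour bovine oligonucleotide arrays held RNA of 1 aged and 1 young cow, in 3 fixed pairs (aged cow 13 with young cow 11, 110 with 7, and 126 with 184). Each pair was hybridised on 2 arrays with the dyes Cy3 and Cy5 exchanged. The labels' protocols state that RNA went through a linear amplification of 2 rounds before labelling. They mention collection by aspiration or after removal of the ovary, and storage by freezing or in a preservative, without tying either to a cow, while the sample characteristics give aspiration throughout. They also mention mother and daughter pairs of cows, without saying that the cows sharing an array are such a pair.

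The deposited scanner files give, per the file headers, the mean and median intensity of each spot and of its local background in both channels on a linear scale, not normalised. They also hold, per the file headers, another column, the number of ignored cells, which marks spots that the image software excluded (42 to 113 per array here). Each file held 45220 spots and 14 summary lines, which were left out. The authors also deposited a table of processed values on a log2 scale. The submitters' processing notes name limma, with no version, and no further step is given in the sources used here. Each column of that table was set against the scanner values of its array over the kept probes. All 6 ran as log2 of aged over young, with r between 0.849 and 0.95 across probes and slopes between 1.02 and 1.13. Their medians lay between -0.0092 and 0.0036, so that each array was centred near 0. The authors' background correction and filter stay unknown. No other column of values was present.

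From the spot means, background was corrected by normexp with an offset of 50 in limma 3.58.1 (R 4.3.3). Ratios were then normalised by loess within each array, with control spots and ignored spots at weight 0, and without a step between arrays. Ignored spots were left out of all later steps. Each ratio was turned to log2(aged / young), the 2 arrays of a pair were averaged, and the 3 pair values were fitted with an intercept by lmFit and eBayes. The pairing comes from the arrays themselves, since both cows of a pair were on the same array, so the pair is in the fit by construction (with no replicate block the count of genes past the threshold stayed at 0). The consensus correlation of arrays within a pair was 0.858. Tests were two-sided, with Benjamini-Hochberg adjustment over all kept probes and a threshold of 0.05. A probe was kept where its signal exceeded the mean + 2 SD of the 153 negative control spots in the channel of at least 1 age group on all arrays. This kept 16242 of 43794 probes. The files carry no flag for saturation, and the brightest probe read 46784 units.

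Probes were named through the platform annotation supplied for them, in which 21790 probes have 1 gene symbol, 0 have several and 22004 have none here. Of 15229 distinct symbols, 14114 stood in the RefSeq gene table (assembly ARS-UCD2.0), and 982 others were updated through an unambiguous synonym. No coordinates are printed, because the annotation names no build. Probes of a gene were tested separately. A gene was represented by its probe with the highest mean log2 signal, which gave 15216 genes, 7436 of them with a kept representative probe. Levels per cow are log2 signals of a channel after loess and Aquantile normalisation, averaged over the 2 dye orientations; values near 8.3 lie at background. They compare cows for a given probe only.

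The 27 gene lists (21 of pathways and granulosa functions and 6 of other cell types) were fixed before the data were examined, as were the tests and the rule for named genes. Lists with at least 5 tested genes (25 of them) were tested by camera with a preset inter-gene correlation of 0.01, and alongside by camera with an estimated correlation and by fry, with Benjamini-Hochberg adjustment over lists. The rule named up to 12 genes per direction past the threshold with the same sign on all 6 arrays. Where fewer than 10 met it, it filled up to 10 per direction with the smallest unadjusted p among genes with an absolute log2 ratio of at least 1 and the same sign on all 6 arrays. It further named up to 4 members of each list with the smallest unadjusted p, and FSHR, LHCGR, CYP19A1, STAR, CYP11A1, HSD3B1, PGR, PTGS2, INHBA, FST and AMH always. Other genes in the text were chosen after their values were seen, and the text says so. A list of 34 epithelial markers was added after the data were examined.

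The fit was tested on simulated data for the aged against young comparison with 3 pairs over 16242 probes, 200 of them changed. With each probe given its own observed spread between pairs, 10% of 2-fold, 34% of 4-fold, 52% of 8-fold and 52% of 16-fold changes were called, with 2 false calls among 76. In simulated arrays with a brightness-dependent dye bias and non-specific signal, a true log2 change of 2 was returned as 1.80 on average, with the right sign for 100% of changed probes. In 500 simulated unchanged lists of 29 genes, drawn independently of each other, 3.4% had p under 0.05 by camera with the preset correlation. This share does not cover lists of correlated genes. In the real data the estimated correlation was 0.361 for oxidative phosphorylation and 0.55 for the inflammatory list. Figures were drawn with matplotlib 3.10.9.

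Alternatives covered the background correction, spot medians, the normalisation, the filter on dim probes, the authors' processed values, the dye and block terms, single dye orientations, an unpaired fit, the slide (read from the names of the deposited scans, not given in the labels), variance options, the summary over a gene's probes, thresholds, and each cow pair left out.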

Results

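The study asked how granulosa cells of the dominant follicle differ between aged and young cows shortly before ovulation. Granulosa cells line the follicle, make oestradiol before the surge of luteinizing hormone (LH), and turn to progesterone production after it. All 6 cows received 25 mg of LH on day 6 of the cycle, and the follicle was collected on day 7, 24 h later. RNA of 3 aged and 3 young cows was compared directly on 6 arrays, as 3 pairs of an aged and a young cow, each with a dye swap. The replicates are separate cows, and n = 3 pairs throughout unless stated. Between 46.5% and 71.9% of probes per channel were above the negative control spots, whose mean signal was 199.8 to 402.1 units, except for 24.6% in the Cy3 channel of aged cow 126. There the negative controls had an SD of 99.2 units (10.1 to 28.2 elsewhere), which made the background filter stricter for the aged group. The median probe read 233.1 to 452.3 units. Many probes were thus close to non-specific signal, which compresses their ratios, and the number of arrays limits the precision.

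Dye-swapped arrays of the same cows repeated each other, while the 3 cow pairs differed from each other. Across kept probes, which are not independent replicates, the turned ratios of the 2 arrays correlated with Pearson r = 0.846 for cows 13 and 11 (Spearman 0.693), 0.845 for cows 110 and 7 (0.754) and 0.624 for cows 126 and 184 (0.523), the last falling to 0.358 with the authors' values and 0.327 with spot medians. Between pairs, r was 0.492 for the pairs of aged cows 13 and 110 (Spearman 0.516), -0.159 for 13 and 126 (-0.101) and 0.03 for 110 and 126 (0.087). By slide numbers read from the names of the deposited scans, which the labels do not state, the arrays of aged cows 13 and 110 shared a slide, and the 2 arrays of cow 126 lay on separate slides with no other array of the series. The number of probes that differed at least 4-fold was 748 in the pair of cow 13, 585 in that of cow 110 and 214 in that of cow 126. In all 3 pairs 39.4% of probes had the same direction (2804 higher and 3591 lower in aged cows), where 25% would if directions were independent between pairs. Probes are correlated and 2 pairs shared a slide, so the excess is no test of an age effect.

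As groups, genes of oxidative phosphorylation and DNA repair were shifted upward and inflammatory cytokine genes downward in the samples of aged cows by camera (adjusted p = 0.962 for each with an estimated correlation). Markers of other cells differed in the same pairs: EPCAM was at -6.77, -4.18 and -0.53 and KRT19 at -5.49, -5.92 and 0.62 in the pairs of aged cows 13, 110 and 126, where oxidative phosphorylation had medians of 0.95, 0.87 and 0.05, the inflammatory list -2.08, -0.63 and 0.42 and leukocyte markers -0.42, -0.23 and 1.11. Among single genes, STAR, which feeds cholesterol into steroid synthesis, had a 5.55-fold ratio, and CXCL2, a neutrophil attractant, a log2 ratio of -1.71 ± 0.21 (SD, n = 3). STAR was highest (3.74) in the pair of aged cow 13, where the granulosa gene GATA4 (4.53) was higher too. No single gene passed the threshold. By limma with Benjamini-Hochberg adjustment, 0 probes were higher and 0 lower in aged cows, and the smallest adjusted p was 0.469. At an unadjusted p under 0.05 there were 884 higher and 788 lower probes, 10.3% of those tested, or 501 higher and 334 lower genes. A fit with a dye term and the cow pair as a random block also gave 0 genes, as did the fit with no replicate block (0). These unadjusted counts were not stable: without the pair of aged cow 110 they were 130 higher and 40 lower genes, and without that of cow 126 988 and 400. Of them 60% were higher, against 80.5% on the median-centred scale, 46.8% with the authors' values, 41.7% without the pair of cow 13 and 40.4% with both channels above background, so the balance of directions was not settled. The genes below, taken by the fixed rule, have the smallest p among those with an absolute log2 ratio of at least 1 and the same sign on all arrays, and none of them passed.

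Among genes with higher ratios in aged cows, the lipid enzymes SGPP1 (sphingosine-1-phosphate phosphatase) and CDS2 (CDP-diacylglycerol synthase) had log2 ratios of 1.44 ± 0.26 (SD, n = 3) and 1.13 ± 0.18. OAZ1, an inhibitor of polyamine synthesis, was at 1.28 ± 0.25, and PYGL, glycogen phosphorylase, at 1.26 ± 0.36. MTDH (1.13 ± 0.06), the ubiquitin ligase UBR3 (1.01 ± 0.13), the proteasome subunit PSMD8 (1.23 ± 0.42), the mitochondrial importer TIMM23 (1.11 ± 0.41), the nuclear pore gene NUP153 (1.04 ± 0.35) and the RNA polymerase I subunit POLR1H (1.02 ± 0.25) completed this group. Each was higher on 6 of 6 arrays with an adjusted p of 0.469. Other probes of MTDH gave smaller ratios of 0.18 and 0.73, and the other probe of UBR3 gave 0.46, that of TIMM23 0.34 and those of POLR1H 0.24 and 0.76. The other probe of CDS2 gave 1.16.

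Among genes with lower ratios in aged cows, the chemokine CXCL2 was at -1.71 ± 0.21, EPB41L4A at -1.45 ± 0.41, PERP, a desmosome component and p53 target, at -1.35 ± 0.37, and AGR3, a disulphide isomerase relative of secretory cells, at -1.32 ± 0.05. FAM13A (-1.29 ± 0.26), the receptor phosphatase PTPRF (-1.20 ± 0.24), the β-globin gene HBB (-1.18 ± 0.32), LOC100299139 (-1.11 ± 0.33), the Notch modifier LFNG (-1.04 ± 0.27) and OSBPL5 (-1.02 ± 0.25) followed. Each was lower on 6 of 6 arrays with an adjusted p of 0.469. LFNG lay in a profile shared by many probes, described under other observations, whose signal may not follow the transcript. The other probe of PERP gave -3.67, with -5.37, -5.09 and -0.54 in the 3 pairs. The other probes of CXCL2 (-1.01) and EPB41L4A (-0.78) were lower on average but higher in aged cow 126 by 0.12 and 0.55.

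**Figure D1:**
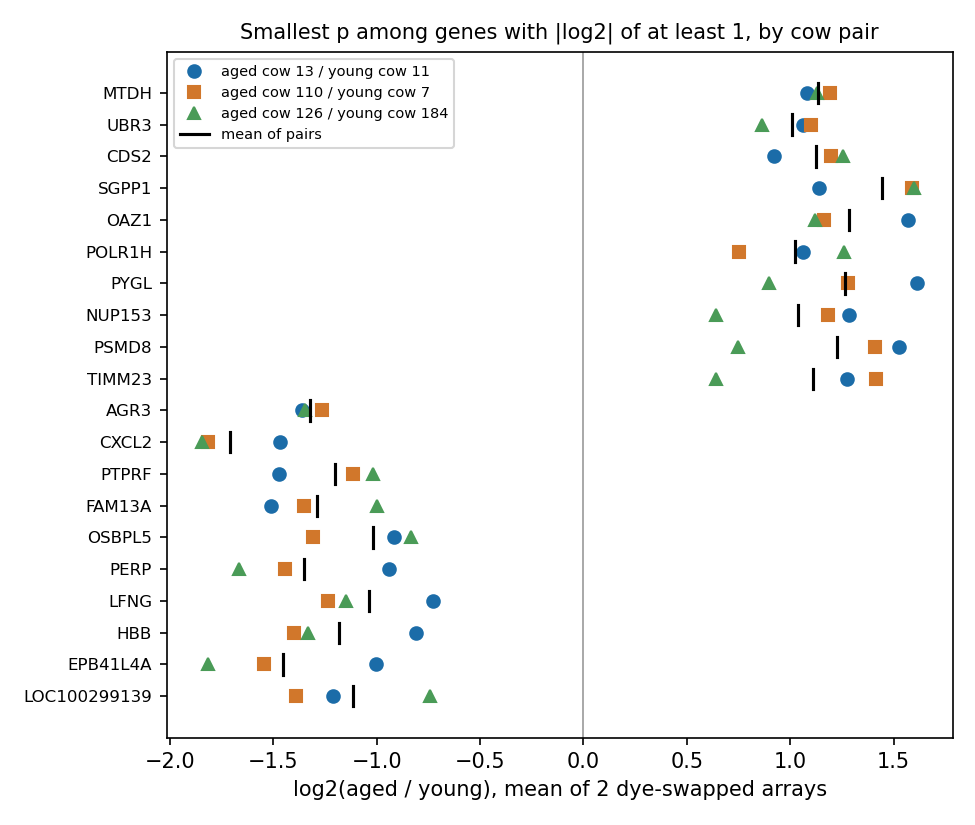
Log2(aged / young) ratios (horizontal axis) of the 10 higher and 10 lower genes with the smallest p among those with an absolute log2 ratio of at least 1 and the same sign on all arrays; each symbol is a cow pair, as the mean of 2 dye-swapped arrays, and the black bar is the mean of the 3 pairs. AGR3 and MTDH vary least between pairs (SD 0.05 and 0.06), and no gene passed the adjusted threshold.

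STAR, which moves cholesterol into mitochondria for steroid synthesis, had the highest mean ratio of the tested steroidogenesis genes and did not pass the threshold. It was at 2.47 ± 1.11 (5.55-fold; between 1.68 and 3.74 in the 3 pairs), on 6 of 6 arrays. The 3.74 came from the pair of aged cow 13, where the granulosa genes GATA4 (4.53) and SERPINE2 (4.38) were higher as well. A different share of granulosa cells in the 2 samples may thus contribute to the ratios of that pair. Its unadjusted limma p was 0.0169 and its adjusted p 0.469, and its other probe gave 2.53. An exact two-sided sign-flip test over 3 pairs gave p = 0.25, the smallest it can give. HSD3B1, which makes progesterone, was at 1.69 ± 1.35 (2.27, 2.65 and 0.14), and CYP11A1, the side-chain cleavage enzyme, was above background on only 5 of 6 aged and 2 of 6 young channels and was not tested (3.10, -2.53 and 0.35). Of 10 tested corpus luteum genes, 5 were higher in all 3 pairs and 0 lower in all, with a median of 0.56 (adjusted p = 0.179). RGN (1.96 ± 1.37) and FDX1 (1.22 ± 1.70), the electron donor of CYP11A1, were the next examples. Of 9 tested steroidogenesis genes, 4 were higher and 3 lower in all pairs (median 0.12, mean 0.36, test towards lower, adjusted p = 0.928), the lower ones being HSD17B7 (-0.90 ± 0.30), NR5A2 (-1.24 ± 0.66) and TSPO (-0.55 ± 0.33). Other probes of NR5A2 gave 0.31 and 2.82, so the direction of this nuclear receptor gene was not settled.

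Of the genes that LH induces before ovulation, TNFAIP6, which stabilises the matrix around the oocyte, was at 6.09 and 5.89 in the pairs of aged cows 13 and 110 and at -0.06 in that of cow 126 (3.97 ± 3.50, adjusted p = 0.531). Its level was 14.99, 15.08 and 15.03 in the 3 aged cows and 15.09 in young cow 184, but 8.90 in young cow 11 and 9.19 in young cow 7, near background. PTX3, another matrix gene, was at 1.68, 5.98 and 0.40, and RGS2, a regulator of G protein signalling, at 1.58, 5.51 and 0.36. Both were chosen after their values were seen. Their levels in young cows 11 and 7 were 8.66 and 9.04 for PTX3 and 8.98 and 9.19 for RGS2. Aged cow 13 was also low, at 10.34 and 10.55. Cows 110, 126 and 184 had 13.39 to 15.02 for PTX3 and 12.7 to 14.71 for RGS2. PTGS2, the inducible prostaglandin synthase, was at 1.31 ± 1.77 (0.61, 3.32 and 0.00), and PGR, the progesterone receptor, at 0.09 ± 0.71. Of 20 tested LH and ovulation genes, 5 were higher and 4 lower in all pairs (median 0.08, mean 0.40, test towards lower, adjusted p = 0.810). NR4A1, an early response gene, was at 1.71 ± 1.10, SERPINA5 at -1.67 ± 0.57 and the growth factor BTC at -2.01 ± 1.56. The other probe of BTC gave -0.04 at a mean log2 signal of 8.49, near background.

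Of the granulosa genes typical of the follicle before the surge, INHBA, the activin subunit, was at 4.61, -3.94 and 0.35 (0.34 ± 4.28, adjusted p = 0.945), with levels of 15.06 in aged cow 13 and 15.40 in young cow 7 and between 10.45 and 11.96 in the other 4 cows. FST, which binds activin, was at 1.54 ± 1.47 (adjusted p = 0.550). CYP19A1, the oestradiol-forming aromatase, was above background on 4 of 6 aged and 5 of 6 young channels and untested; its level was 13.01 in aged cow 13, 9.68 in young cow 7 and 8.36 to 8.48 elsewhere. FSHR (above background on 4 aged and 1 young channel), LHCGR (4 and 1) and AMH (5 and 3) were also untested, with mean ratios of -0.13, 0.34 and 0.12. The 9 tested genes of this list had a median of 0.34 (4.10, 0.01 and -0.09 by pair; adjusted p = 0.928), with GATA4 at 1.76 ± 2.67 and SERPINE2 at 1.44 ± 2.56. In young cow 11 the abundant inhibin subunit INHA, chosen after its values were seen, was at 10.44, against 14.87 to 15.16 in the other 5 cows.

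Some markers of other cell types were high in single cows. Chosen after their values were seen, the epithelial adhesion gene EPCAM (ratios of -6.77 and -4.18), the keratin KRT19 (levels of 14.69 and 15.38) and the cornified envelope gene PPL (levels of 14.66 and 15.08) were high in young cows 11 and 7. In the 3 aged cows and young cow 184, EPCAM lay between 8.23 and 9.78, KRT19 between 9.20 and 12.16 and PPL between 8.43 and 10.51. The 17 tested leukocyte markers had medians of -0.42, -0.23 and 1.11 in the 3 pairs (0.08 over pairs, mean -0.06, test towards lower, adjusted p = 0.747). TYROBP, chosen after its values were seen, reached 13.87 in aged cow 126, against 8.25 to 10.61 in the others. The leukocyte examples by the rule were GZMB (-1.12 ± 0.56), PTPRC (-0.65 ± 0.50), AIF1 (0.76 ± 0.78) and CD163 (0.72 ± 0.97). GZMB, at levels of 12.05 to 13.96 in all 6 cows, lay in the shared probe profile described under other observations. Its signal may not follow the transcript. Theca (7 genes, median -0.03, adjusted p = 0.306), endothelial (5 genes, -0.07, 0.333) and fibroblast and smooth muscle markers (10 genes, -0.05, mean 0.21, test towards lower, 0.727) showed no shift past the threshold. Several of these markers were near background, with mean log2 signals of 8.43 to 8.66 for EGFL7, ECSCR, ROBO4 and VWF, 8.56 for INSL3 and 8.74 for COL1A1. Such members could hardly show a shift. The theca marker ALDH1A1 was at -4.37, -4.43 and 0.43. Only 2 erythrocyte markers (HBB and SLC4A1, median -0.98) and 4 oocyte markers (median -0.04) passed the filter, too few to test. The oocyte markers had mean log2 signals of 8.51 to 8.82, near background.

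**Figure D2:**
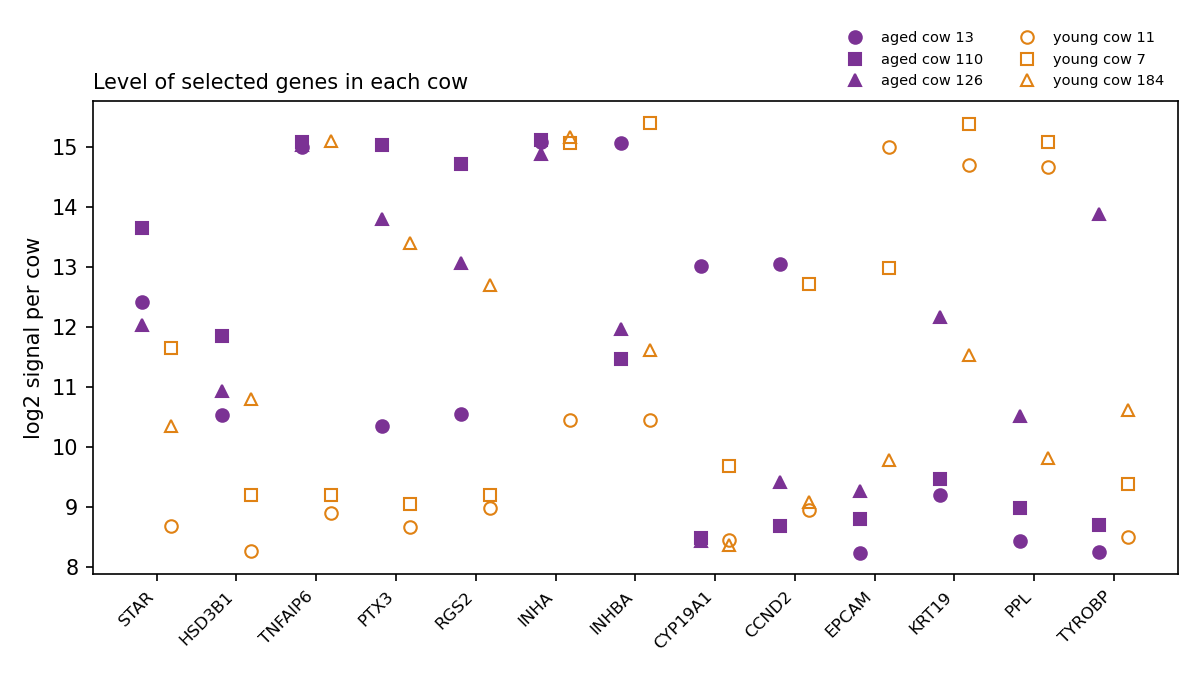
Log2 signal (vertical axis; about 8.3 is background) of 13 genes in each cow, with aged cows filled and young cows open and the same symbol for the cows of a pair. TNFAIP6 is near 15 in all cows but young cows 11 and 7, where EPCAM, KRT19 and PPL are highest; several genes were chosen after their values were seen, and levels compare cows within a gene only.

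Genes of oxidative phosphorylation were shifted upward as a group in aged cows. Of 29 tested members, 12 were higher and 0 lower in all 3 pairs, with a median of 0.63 (0.95, 0.87 and 0.05 by pair; camera adjusted p = 4.84e-05). The call was lost when the correlation between members was estimated (adjusted p = 0.962 with an estimated correlation). The aged cows of the same 2 pairs also had lower EPCAM and KRT19. No single member passed over all probes (0) or adjusted over the list alone (0). With the ages exchanged in 1 pair, 4 to 8 lists passed by the same test, against 3 with the real ages. Such a call does not by itself tie a shift to age. COX5A of complex IV was at 0.68 ± 0.16, SDHB of complex II at 0.66 ± 0.18, UQCRC2 of complex III at 0.60 ± 0.26 and NDUFA9 of complex I at 0.48 ± 0.11. The other probes of COX5A gave 0.14, 0.43 and 0.04.

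DNA repair genes were also shifted upward by camera, by a smaller amount. For scale, the representative probes of all genes with several kept probes, counted once per other probe, had a median of 0.20. Of 18 tested members, 8 were higher and 0 lower in all pairs, with a median of 0.24 (0.52, 0.13 and 0.13 by pair; adjusted p = 0.037; adjusted p = 0.962 with an estimated correlation). APEX1, the base excision endonuclease, was at 0.59 ± 0.10, the mismatch repair gene MSH6 at 0.40 ± 0.10, MRE11 at 0.43 ± 0.18 and PARP1 at 0.60 ± 0.36. APEX1, MSH6 and MRE11 were dim, with mean log2 signals of 8.75, 8.92 and 8.83. They were above background on 6 of 6 aged but only 3, 5 and 5 of 6 young channels. No member of the list passed over all probes or adjusted over the list alone. The call ended in 8 of 20 other fits: without the pair of aged cow 13 (median 0.14, adjusted p = 0.743) or 126 (median 0.37, 0.0517), with probes above background in both channels of all arrays (0.281), with aged cows in Cy3 only (0.211), with the slide as a random block (0.133), with spot medians (0.0931), with the authors' values (0.0747) and with median centring (0.0525). With no replicate block it was 0.0352. The epithelial genes EPCAM and KRT19 were lower in aged cows 13 and 110. The medians of this list did not follow them, being 0.13 in the pairs of both cow 110 and cow 126.

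Inflammatory cytokines and NF-κB targets were shifted downward by camera with the preset correlation, in the pairs of aged cows 13 and 110 but not 126. The 12 tested members had a median of -0.79 (-2.08, -0.63 and 0.42 by pair; adjusted p = 0.00762; adjusted p = 0.962 with an estimated correlation), with 3 lower and 0 higher in all pairs. CXCL2 (-1.71 ± 0.21) was the single member to pass when adjusted over the list alone (adjusted p = 0.00773). The antimicrobial protein LTF was at -2.82 ± 2.19, the complement factor CFB at -2.12 ± 2.59 and the chemokine CXCL5 at -1.94 ± 1.68. In aged cow 13 the levels of CFB (8.28) and CXCL5 (8.14) lay at background, so the size of their ratios is uncertain. The level of LTF was 15.28 and 14.52 in young cows 11 and 7, in which EPCAM and KRT19 were also high. Without the pair of aged cow 13 the median was 0.07 (adjusted p = 0.800), and without the filter on dim probes -0.03 (adjusted p = 0.297). With the slide as a random block the adjusted p was 0.236, with no replicate block 0.00342, and within the slide that held the pairs of cows 13 and 110, which equals leaving out cow 126, it was 0.000122. In that fit the leukocyte markers had a median of -0.46 (camera adjusted p = 0.00723; over all 3 pairs adjusted p = 0.962 with an estimated correlation), and their medians of -0.42, -0.23 and 1.11 rank the 3 pairs as those of the inflammatory list do.

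Other groups did not pass. EGF-like ligands and MAP kinase feedback genes came nearest (15 tested, 0 higher and 4 lower in all pairs, median -0.24, adjusted p = 0.0531), with IER2 at -0.78 ± 0.23, FOSB at -0.92 ± 0.58 and SPRY1 at -0.97 ± 0.73. The other probe of SPRY1 gave -0.03 at a mean log2 signal of 8.45, near background. FOSB, and NDRG1 named below, lay in the shared probe profile described under other observations. The 23 cell cycle genes had a median of 0.75 (2.32, -0.32 and 0.32 by pair, adjusted p = 0.124), with PCNA at 1.19 ± 1.02, CCNA2 at 1.11 ± 1.23, and the replication helicase genes MCM2 (0.33 ± 0.13) and MCM6 (0.25 ± 0.03); without the pair of aged cow 110 the list passed (adjusted p = 6.48e-06), as it did with no replicate block (0.0352) and without the filter on dim probes (0.00804), and with an estimated correlation its adjusted p was 0.962. The 23 glycolysis and hypoxia genes had a median of 0.47 (adjusted p = 0.306), with PGAM1 at 1.43 ± 0.63, HK1 at 0.31 ± 0.08, PFKFB3 at -0.92 ± 0.23 and NDRG1 at -1.08 ± 0.53. The other probe of HK1 gave -0.05, and both its probes were dim, with mean log2 signals of 8.77 and 8.6. The 13 heat shock genes (median 0.27, 0.365) included HSPA8 at 1.12 ± 0.59 and HSP90AA1 at 1.02 ± 0.73. The 25 antioxidant genes (0.26, 0.928) included PRDX1 at 1.71 ± 1.51, PRDX3 at 1.22 ± 0.92 and the stress regulator NFE2L2 at 0.67 ± 0.40. The 12 ageing and senescence genes (0.11, 0.928) included LMNB1 at -1.27 ± 0.69 and SIRT1 at 0.83 ± 0.85. LMNB1 (-0.57, -1.28 and -1.95 by pair) lay near the shared probe profile, though outside its bounds. Its signal may not follow the transcript either. The 28 ribosomal protein genes had a median of -0.06 (adjusted p = 0.154).

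Among the remaining lists, the 17 genes of cholesterol synthesis and uptake had a median of -0.01 (mean 0.02, test towards lower, adjusted p = 0.333), with SQLE at 0.65 ± 0.37 and SREBF2 at -0.89 ± 0.57. SREBF2 too lay in the shared probe profile described under other observations. Its other probe gave -0.42, with 0.92 in the pair of aged cow 126. The 19 matrix and protease genes (median -0.08, mean 0.28, test towards lower, 0.748) included COL4A1 at 1.56 ± 1.88, MMP2 at -0.91 ± 0.40 and HSPG2 at -1.22 ± 0.61. MMP2 (-0.47, -1.24 and -1.04 by pair) and HSPG2 (-0.56, -1.33 and -1.76) lay near that profile, though outside its bounds. Their signal may not follow the transcript either. The 17 apoptosis and p53 genes (-0.03, mean 0.13, test towards lower, 0.360) included GADD45B at 2.43 ± 1.88. The 17 unfolded protein response genes (0.03, mean 0.05, test towards lower, 0.928) included MANF at 0.94 ± 0.59. The 9 interferon response genes (-0.58, 0.306) included CXCL10 at -1.01 ± 0.86 and STAT2 at 0.78 ± 0.33. The 8 insulin-like growth factor genes (-0.002, mean 0.46, test towards lower, 0.928) included IGF2 at 1.72 ± 2.01 and IGFBP7 at 2.32 ± 3.42. The other probe of IGF2 gave 0.61. The 20 TGF-β family and SMAD genes (0.19, 0.928) included ID2 at 1.38 ± 1.10 and BMP7 at -1.14 ± 0.97. With an estimated correlation 0 of the 25 lists passed, as with fry (0), while 6 had an unadjusted camera p under 0.05.

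**Figure D3:**
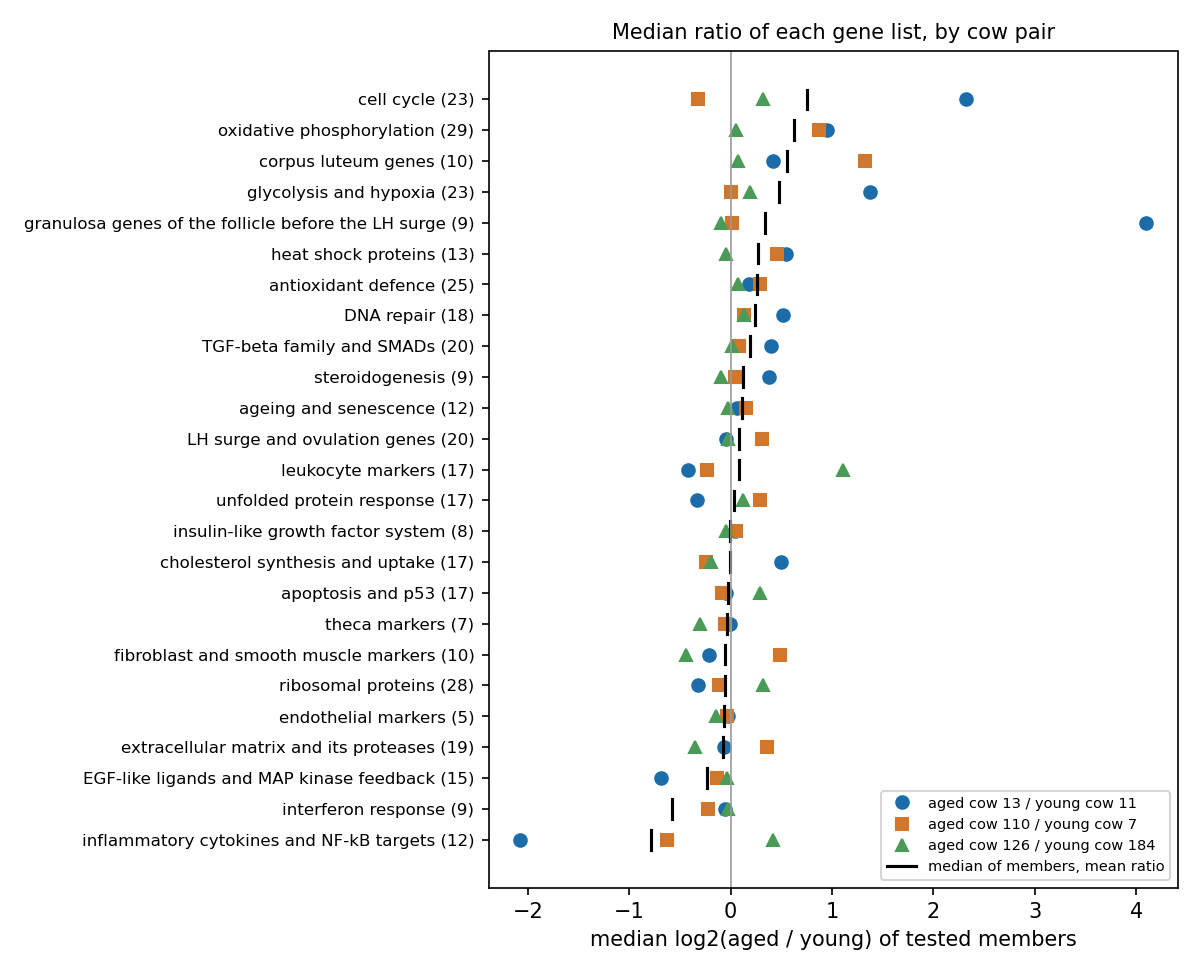
Median log2(aged / young) of the tested members of each gene list (horizontal axis), with the number of members in brackets; symbols are the medians within a cow pair and black bars the median of the members' mean ratios. The oxidative phosphorylation medians are 0.95, 0.87 and 0.05, and the inflammatory list spans -2.08 to 0.42.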

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

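The comparison of the 2 arrays of cows 126 and 184 and the tests on 5 granulosa genes were chosen after the results were seen. The test for exchanged RNA and the epithelial marker list were written before their values were computed, though after single genes such as AGR3, LTF and CDH1 had been looked at.

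The ratio of 3360 probes differed between the 2 dye orientations (limma on the difference within each pair, adjusted p under 0.05), a dye effect that cancels in the mean of a pair; over all kept probes its median absolute size was 0.10 (log2). Control spots not used in any comparison were far brighter than the negative controls, by 41.4 times for the E1A spike-in spots, 29.2 times for those named DCP and 45.2 times for those named GE.

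The pair of cows 126 and 184 did not share the changes of the other 2 pairs, whose ratios correlated with r = 0.492. A slide effect stays open: its 2 arrays, on different slides by the names of the deposited scans, correlated with r = 0.624, above the bound of 0.5 against such an effect, but with r = 0.358 with the authors' values and 0.327 with spot medians, below it. An exchange of aged and young RNA in this pair, which would reverse all its ratios, would not alone account for the pattern. Its r was -0.159 with the pair of cow 13 and 0.03 with that of cow 110. Reversing its signs would leave both far from the 0.492 between those 2 pairs. Whether RNA was exchanged at all stays open. Of 193 probes that differed at least 4-fold the same way in the other pairs, 64.2% went the opposite way in this pair, fewer than the 80% set in advance for an exchange and more than the 60% set against it. No biological explanation was tested.

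TNFAIP6 was low in young cows 11 and 7 only. PTX3 and RGS2 were low in these 2 cows and, to a smaller extent, in aged cow 13 (10.34 and 10.55). For cow 7, 5 granulosa genes had a median ratio of 0.053 against aged cow 110 but went both ways (GATA4 1.54, CCND2 -4.05, INHBA -3.94). INHA (15.06) and SERPINE2 (14.98) were near the brightest signals of the arrays. None of the 5 was lower in cow 7 by nearly as much as TNFAIP6 (5.89), PTX3 (5.98) and RGS2 (5.51). These values argue against a smaller share of granulosa cells as the only account of the 3 low genes. A smaller contribution stays open. For cow 11 the same 5 genes had a median ratio of 4.53. INHA (10.44), SERPINE2 (10.78) and GATA4 (8.8) were lower there than in any other cow. CCND2 (8.95) and INHBA (10.45) differed less from cows 110, 126 and 184 (8.67 to 9.41 and 11.46 to 11.96), and both were high in aged cow 13. A smaller share of granulosa cells may account for the low values of cow 11. Epithelial cells are a candidate source of the rest that was not settled: the 10 of 34 epithelial markers that passed the background filter had a median ratio of -2.80 against aged cow 13 (-0.10 over all 33 on the array, most of them near background in cow 11), with KRT19 and PPL at 14.69 and 14.66, while ELF3, LAD1 and S100A14 stayed between 8.48 and 8.83 and CDH1 at 8.37. The 10 markers had medians of -2.28 for cow 7 and -0.21 for cow 184 (-0.16 and 0.00 over all 33), the filter, which asks for signal in all channels of an age group, helped to choose them, the origin of such cells is not known, and no biological explanation was tested.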

How the results depend on the processing

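The count of 0 genes in each direction held under 19 of the 20 other fits, each cow pair left out included. With arrays taken as independent, which counts the dye swap as a replicate, 52 genes were higher and 11 lower. An unadjusted p under 0.05 with 1.5-fold gave 245 higher and 295 lower genes. Without the pairing (no replicate block, levels of 3 aged against 3 young cows) 0 genes were higher and 0 lower, with 3 lists higher and 1 lower. Of the lists, 2 were higher and 1 lower. Only 1 was higher with median centring, with probes above background in both channels on all arrays, with the authors' values, with aged cows in Cy3 only, with the slide as a block and with spot medians. Lower were 2 lists without background correction, with local background subtracted, with both channels above background, with the authors' values, with the pair as a random block, with aged cows in Cy3 only, with background from negative controls and with spot medians, and 0 without a filter and with the slide as a block. With an estimated correlation or fry 0 were higher and 0 lower. Leaving out a cow pair gave 1 to 4 higher and 1 to 4 lower. Oxidative phosphorylation passed under 20 of 22 alternatives, inflammatory cytokines under 17 and DNA repair under 12. Every passing fit kept the preset correlation of 0.01, so these counts do not test that setting. The alternatives without it, an estimated correlation and fry, called none of these lists. Other lists passed at times: the EGF-like list under 10, and without a single cow pair glycolysis (adjusted p = 0.0122), leukocyte markers (0.00723), ribosomal proteins (0.00103) and cholesterol synthesis (0.025). The correlation of dye-swapped arrays fell to 0.691, 0.632 and 0.358 (pairs 13, 110, 126) with the authors' values and to 0.669, 0.625 and 0.327 with spot medians. The cause was not tested. No call reversed; of all comparisons with the values reported, the direction of the list test changed in 42 of 545, the sign of the list median in 61 of 545 and the sign of a gene's ratio in 7 of 515. Spot medians and background from negative controls were chosen after seeing the data. Dim probes limit all of this.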

Other observations

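The tests in this part were written before their values were computed; the count of probes with a shared profile was made after the probes were seen.

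The genes here were chosen after their values were seen. In the pair of aged cow 126 SELP was at 5.01, CD5L at 4.79, CCL24 at 4.71, ALOX15 at 4.49, the keratin KRT78 at 4.22 and ANG2 at 4.03, and LAPTM5 and BOLA-DRA reached levels of 13.94 and 13.88 in this cow, while the fixed leukocyte list did not pass over the 3 pairs (adjusted p = 0.747). KRT78 went the other way in the pairs of aged cows 13 and 110, at -5.01 and -5.34. Young cow 7 also had the basal keratins KRT5 (10.63) and KRT14 (12.04) and SFN (11.35) above the other cows, which lay at 8.26 to 8.51. Young cow 11 instead had NTS, AGR2 and CLCA1 lower in its aged partner by ratios of -6.98, -6.83 and -6.72, with ratios of 0.71, -1.55 and 1.40 in the pair of young cow 7. SAA3, an acute phase protein, was at 15.18 in young cow 11 and between 8.66 and 10.78 elsewhere.

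Many probes with lower ratios in aged cows shared a single profile. The 788 probes lower at an unadjusted p under 0.05 had median ratios of -0.48, -1.24 and -1.35 in the 3 pairs, and 305 of them (38.7%) lay within 0.3 of these medians in every pair. Over all kept probes 316 did, against 5 around the mirrored profile, and 66.8% of the 316 had no gene symbol, against 43.3% of kept probes. Genes of other tissues such as CHRNA1, NEFM, FABP1 and GRIA4 were among them, as were LFNG, GZMB, NDRG1, SREBF2, FOSB, GSTM1 and DES. A candidate explanation is signal of the probe that does not follow the transcript, such as cross-hybridisation. Of 105 other probes of the genes lower at an unadjusted p under 0.05, 60% had the same sign, with a median of -0.02 where the representative probes had -1.06, and 4.8% had the same sign with a p under 0.05; the 60% lies exactly at the bound set in advance for this explanation. Of 146 other probes of the genes with higher ratios, 73.3% had the same sign, between the bounds set in advance, with a median of 0.18 against 0.63, and 27.4% had the same sign with a p under 0.05, so that this explanation was not decided for them. Over all genes with several kept probes 68.8% of other probes had the sign of the representative probe.

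With 3 pairs there are 4 assignments of age within pairs, too few for a share under 0.05. The real assignment gave 1672 probes at an unadjusted p under 0.05, the most of the 4 (1 of 4), and the highest of the others was 1566, with cow 126 and cow 184 exchanged. For genes past the adjusted threshold all 4 of 4 gave 0. For gene lists the real assignment gave 3 and the highest of the others 8, so that all 4 of 4 gave at least as many.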
